A study of Homo sapiens with 4 samples.

How the data were processed

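RNA-seq was available for 4 libraries of the human hiPSC line WTC0011, 2 from 2D culture and 2 from 3D scaffold culture. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was enriched for poly(A) RNA with oligo(dT) beads, fragmented, reverse transcribed with random primers, and made into circular DNA libraries after PCR. HISAT2 version 2.21, an aligner, is named in the submitters' processing notes. The quantifier, genome build, annotation and strandedness are not given in the sources used here. Per the file headers, the deposited values are TPM, with 1 library per file. The values of each library sum to the full TPM scale over 18280 genes, of which 508 are listed at 0 in all 4 libraries. The genes carry NCBI Gene IDs, and 18270 of them were found in the RefSeq gene table. TPM keeps no depth, so the depth of each library is unknown and no counting interval or detection limit can be given. TPM also divides by transcript length and fixes the total, so a rise in some genes lowers the share of all others.

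Tests were chosen before the data were examined, for counts and for normalized values. Since the files hold TPM, the test for normalized values was used. Genes with at least 1 TPM in at least 2 of the 4 libraries were kept (14185). Values were log2 transformed after adding 1, and 3D was compared with 2D in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with trend and robust variance moderation, and with no block. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, with no fold minimum. All tests are two-sided unless stated. With 2 libraries a group each gene has 2 residual degrees of freedom, and the moderated test borrows its spread from the other genes.

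The procedure was tested on simulated data with 200 changed genes of known size among the 14185, over 20 simulations. With variances drawn from the fitted prior, it recovered 28.9% of genes changed by 0.3 on the log2 scale, 85.3% at 0.6 and 99.3% at 1.2, and 4.86% of calls were false. With the moderated variance of each gene as fitted to these data, it recovered 47.1%, 93.4% and 99.9%, and 12.3% of calls were false. The second rate is above the nominal 5%, so calls near the threshold may be less certain than their adjusted p states. In the data 35.1% of tested genes are called, far more than the 200 changed in simulation, so neither false rate carries over directly. The second kind of simulation was run first and the other added after its rate was seen; single simulations of both kinds, run before these averages, gave higher false rates.

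There were 46 gene lists fixed before the data were examined, covering pluripotency, neuron types and regions, other cell types, matrix and adhesion, signalling, stress and RNA quality. Of their 962 entries, 947 matched a symbol in the files, 5 matched through a RefSeq synonym, and 10 did not match. Lists with at least 5 tested members (43) were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each was also tested with an estimated correlation and with limma's fry. The numbers of changed members are given over all genes, and for some lists adjusted over the list alone.

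Genes were named by a rule fixed before the data were examined. It takes 14 genes whatever their values (POU5F1, NANOG, SOX2, LMX1A, FOXA2, EN1, TH, NR4A2, DDC, TUBB3, MAP2, GFAP, COL1A1, MKI67). It takes the 8 largest rises and 8 largest falls among changed genes of at least 5 TPM on average whose 3D libraries lie on the same side of both 2D libraries, leaving out LOC, LINC, antisense and clone names. From each list it takes up to 4 changed members with the smallest adjusted p. List members that moved against their list (ALDH1A1, HOMER1, SEMA6A, IFI6, PROM1, NDRG1, BNIP3L), fallen endothelial genes beyond the rule, low markers given as values, and genes named beyond the lists in the closing section were chosen after their values were seen.

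The alternatives tried were pseudocounts of 0.1 and 0.01, no expression filter, a stricter filter (5 TPM in every library of 1 group), median ratio scaling, limma without trend, the replicate number as a block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. A loess correction of each library for transcript length and GC content, and limma without robust moderation, were added after seeing the data. Tests and scalings that need counts had also been listed and were not run, because the files hold TPM. Figures were drawn with matplotlib 3.10.9.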

Results

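Poly(A) RNA was sequenced from 4 libraries of the human induced pluripotent stem cell (hiPSC) line WTC0011. Of these, 2 came from conventional flat culture (2D) and 2 from culture in a 3D scaffold, a support in which cells grow in depth as well as across a surface. The series describes hiPSC reprogrammed under both conditions. The labels give the cell type as hiPSC and the tissue as neuron, and the stage of culture is not given in the sources used here. Each library holds values for 18280 genes as TPM, the length-corrected share of each gene among the transcripts of its library. TPM keeps no record of sequencing depth, so the depth of the 4 libraries is unknown and no counting interval is given. Errors below are the SD between the 2 libraries of a group (n = 2) or the standard error of a log2 fold change. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes near 1 TPM. The files name no genome build, so genes are given by symbol and NCBI Gene ID without coordinates.

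Both pluripotency and neuronal genes were expressed at high levels in all 4 libraries. POU5F1 (Gene ID 5460), a core pluripotency transcription factor, averaged 1165 TPM in 2D and 746.5 TPM in 3D. TUBB3 (Gene ID 10381), the neuronal tubulin, averaged 773 TPM in 2D and 1061 TPM in 3D. Between 14050 and 14074 genes reached 1 TPM in each library. Mitochondrially encoded transcripts took 9.63% to 10.1% of TPM, with the 2 groups overlapping. Across genes, log2(TPM + 1) correlated at r = 0.996 between the 2D libraries and also between the 3D libraries. Between groups it correlated at 0.986 to 0.991. Genes are not independent replicates, so these values describe similarity only.

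The design gives 1 comparison, which asks how the transcriptome of these cells differs between 3D scaffold and 2D culture. In 3D, genes of the pluripotent state, epithelial genes and cell cycle genes were lower. Neuronal, synaptic and axon guidance genes were higher, as were 11 of 15 tested genes of the midbrain floor plate list, although OTX2 fell. These list-level calls rest on camera's preset correlation, and each was lost with an estimated correlation (adjusted p = 0.604 to 0.611). The shifts were small and broad. Pluripotency genes fell to about 64% of their 2D level (median of the list's members of at least 5 TPM, 63.9%), while TUBB3 was 1.37-fold higher. TTR, a thyroid hormone carrier, rose 2.24-fold, and TRH, thyrotropin-releasing hormone, 3.94-fold. The folds and the percentage given here are ratios of mean TPM, without the added 1.

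By limma, 4979 of 14185 tested genes changed at an adjusted p under 0.05, of which 2862 were higher and 2117 lower in 3D. With median ratio scaling the majority turned, with 2246 higher and 2479 lower. Leaving out 2D replicate 1 lowered the number to 3198 and leaving out 2D replicate 2 to 2769. The median size of the changes was 0.32 on the log2 scale, and 86.0% of the changed genes moved by less than 0.5. Only 34 changed by at least 1 on the log2(TPM + 1) scale, 26 up and 8 down. This count leaves out some genes whose TPM more than doubled, such as NHLH2 (3.75 to 8.17 TPM). For scale, the 2 libraries of a group differed by a median of 0.074 in 2D and 0.077 in 3D over all tested genes. The median of 0.32 covers only genes chosen for having changed, so it is not directly comparable. In all 4979 changed genes both 3D libraries lay on the same side of both 2D libraries, as they did in 70.3% of all tested genes. No source used here says whether the libraries of a group came from separate cultures, so the p-values may measure technical spread alone.

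Pluripotency genes fell together. Of 24 tested members of the list, 20 fell, none rose and 4 did not pass, and adjusted over the list alone 21 fell. The list passed limma's camera test (median log2 fold change -0.64, adjusted p = 5.29e-14), but not with an estimated correlation between genes (adjusted p = 0.604). POU5F1 went from 1165 ± 11.2 TPM in 2D to 746.5 ± 77.1 TPM in 3D, a log2 fold change of -0.65 ± 0.065 (adjusted p = 0.000623). NANOG (Gene ID 79923), another core factor of pluripotency, went from 39.0 ± 3.24 to 24.8 ± 3.30 TPM (log2 fold change -0.64 ± 0.094). DNMT3B, the de novo DNA methyltransferase of early embryonic cells, fell from 267.5 ± 13.4 to 172.6 ± 13.9 TPM. ZFP42, also known as REX1, fell from 68.4 ± 4.07 to 40.8 ± 4.41 TPM. SOX2 (Gene ID 6657), which pluripotent and neural progenitor cells share, did not pass, at 235.6 ± 5.11 TPM in 2D and 232.1 ± 0.0212 TPM in 3D (adjusted p = 0.722). Among the genes of common reprogramming vectors, 4 of 7 fell (POU5F1, NANOG, LIN28A and MYC) and none rose (adjusted p = 0.00317, and adjusted p = 0.604 with an estimated correlation). These 4 genes also form part of what a pluripotent cell expresses, and TPM cannot separate endogenous from vector transcripts.

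**Figure D1:**
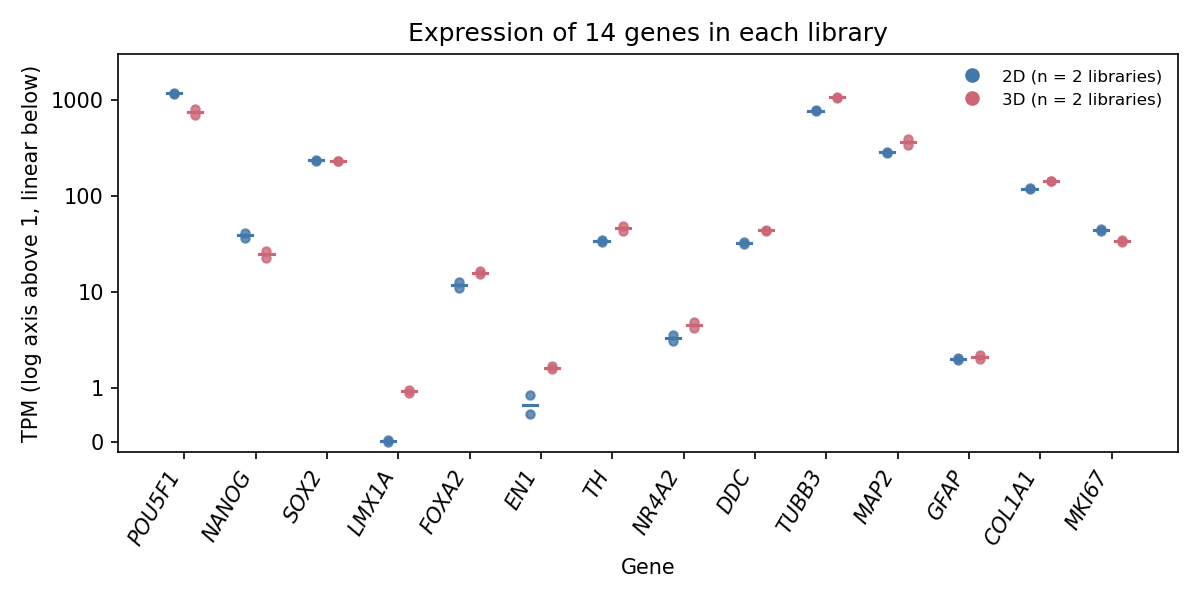
TPM of 14 genes chosen before the data were examined, in each 2D library (blue) and 3D library (red), with points for libraries and bars for means of 2. The axis is logarithmic above 1 TPM and linear below. POU5F1 lay between 692 and 801 TPM in 3D and above 1157 TPM in both 2D libraries, TUBB3 was higher in both 3D libraries, and SOX2 and GFAP did not pass the test.

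Epithelial genes and most tested endothelial genes were lower in 3D as well. Of 13 tested epithelial genes, 12 fell and none rose (median -0.63, adjusted p = 2.13e-10, and adjusted p = 0.604 with an estimated correlation), and 12 fell when adjusted over the list alone. The epithelial cadherin CDH1 went from 66.5 ± 1.70 to 42.6 ± 1.42 TPM and the keratin KRT18 from 288.6 to 181.6 TPM. Pluripotent stem cells express both. Of 7 tested endothelial genes, 5 fell and 1, CLDN5, rose (median -0.60, adjusted p = 0.0108, and adjusted p = 0.611 with an estimated correlation). The genes that fell were KDR, FLT1, EGFL7, ERG and TEK. Without 2D replicate 2, ERG (log2 fold change -0.50, adjusted p = 0.113) and TEK (-0.49, adjusted p = 0.102) missed the threshold. TEK also missed it without 2D replicate 1 (-0.47, adjusted p = 0.107) or 3D replicate 1 (-0.45, adjusted p = 0.0737), as CLDN5 did without 2D replicate 1 (0.37, adjusted p = 0.0503). The endothelial markers PECAM1 and CDH5 stayed under 0.3 TPM in every library and were not tested. Among the largest falls of genes of at least 5 TPM were those of MT1E (metallothionein, log2 fold change -1.02 ± 0.088), C19orf33 (-0.99), DPEP1 (-0.88), KDF1 (-0.85), TMPRSS2 (-0.77), GRB7 (-0.76) and SCGB3A2 (-0.76). MT1E has close copies that share sequence with it, so its value is uncertain.

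Cell cycle genes were lower in 3D. Of 30 members, 26 fell and none rose (median -0.34, adjusted p = 2.12e-14, and adjusted p = 0.604 with an estimated correlation), and 27 fell when adjusted over the list alone. The proliferation marker MKI67 (Gene ID 4288) went from 44.5 ± 1.93 to 34.1 ± 0.778 TPM (log2 fold change -0.37 ± 0.060, adjusted p = 0.00105). The mitotic kinase AURKB and cyclin CCNB1 fell by 0.50 and 0.40 on the log2 scale. Ribosomal protein genes fell slightly, with 20 of 48 lower and none higher (median -0.086, adjusted p = 8.36e-07, and adjusted p = 0.614 with an estimated correlation). All genes with an RPL or RPS ribosomal protein symbol, a wider set than the list, took 16.1% to 16.4% of TPM in 2D and 15.2% to 15.6% in 3D. In the glycolysis and hypoxia list 13 of 29 genes fell and 4 rose (adjusted p = 0.00911, and adjusted p = 0.614 with an estimated correlation). Lactate dehydrogenase LDHA and the glucose transporter SLC2A3 were among those that fell, and NDRG1, P4HA1, BNIP3L and ENO2 rose. In the interferon list 8 of 24 genes fell and 2, IFI44 and IFI6, rose (adjusted p = 0.00351, and adjusted p = 0.604 with an estimated correlation). IFI6 lost its call without 2D replicate 2 (0.0681) or without a variance trend (0.0598). IFITM1, BST2 and IFITM2, the fallen members with the smallest adjusted p, include genes that pluripotent cells express without interferon.

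Neuronal genes were higher in 3D. Of 22 pan-neuronal genes, 18 rose and 1, THY1, fell (median 0.38, adjusted p = 3.3e-08, and adjusted p = 0.604 with an estimated correlation). TUBB3 rose from 773 ± 21.3 to 1061 ± 23.3 TPM (log2 fold change 0.46 ± 0.037, adjusted p = 6.6e-05). The dendritic protein MAP2 (Gene ID 4133) rose from 284.0 ± 1.01 to 365.6 ± 32.5 TPM, and STMN2, a regulator of microtubules in growing axons, from 537 to 812 TPM. Of 25 synapse genes, 17 rose and 1, HOMER1, fell (adjusted p = 2.41e-05, and adjusted p = 0.611 with an estimated correlation). The vesicle proteins SYT4, VAMP2 and SYP were among those that rose, and the call of HOMER1 was lost without 2D replicate 2 (0.0926) or 3D replicate 1 (0.0631). Of 27 axon guidance genes, 19 rose and 1, SEMA6A, fell (adjusted p = 3.88e-06, and adjusted p = 0.611 with an estimated correlation), with SLIT1, NTN1 and ROBO3 among those higher. SEMA6A was not past the threshold without 2D replicate 2 (0.161) or without a variance trend (0.0906). Of 21 neuronal ion channel genes 5 rose, of which 1 was left when adjusted over the list alone, and the list did not pass (adjusted p = 0.0514; 0.0217 with no expression filter, 0.0276 with median ratio scaling, 0.0249 without 2D replicate 2 and 0.0485 without 3D replicate 2).

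Genes of several neuron types rose alongside each other. In the dopaminergic list 10 of 17 genes rose and 1, ALDH1A1, fell (median 0.26, adjusted p = 0.00583, and adjusted p = 0.604 with an estimated correlation). TH (Gene ID 7054), the rate-limiting enzyme of dopamine synthesis, went from 33.8 ± 1.00 to 46.4 ± 4.15 TPM (log2 fold change 0.44 ± 0.069, adjusted p = 0.000942). DDC, the next enzyme of the pathway, went from 32.6 ± 1.14 to 44.0 ± 0.962 TPM. ALDH1A1 lost its call without 2D replicate 1 (0.102), 2D replicate 2 (0.16) or 3D replicate 1 (0.213), and with no expression filter (0.0512). DLK1 rose from 100.9 to 173.1 TPM. NR4A2 (Gene ID 4929), a factor of dopaminergic neurons, went from 3.34 to 4.60 TPM (adjusted p = 0.0401), a call lost without 2D replicate 1 (0.208), 2D replicate 2 (0.0708) or 3D replicate 1 (0.199), with median ratio scaling (0.056) and with no expression filter (0.0686). The dopamine transporter SLC6A3 stayed under 0.3 TPM in every library. Of 15 tested midbrain floor plate genes 11 rose and 1, OTX2, fell (median 0.38, adjusted p = 0.002, and adjusted p = 0.604 with an estimated correlation). SPON1, FOXA1 and SHH had the smallest adjusted p among those that rose. FOXA2 (Gene ID 3170) went from 11.9 ± 1.30 to 16.0 ± 0.764 TPM (adjusted p = 0.00615; 0.0615 without 2D replicate 2). EN1 (Gene ID 2019) went from 0.695 ± 0.247 to 1.65 ± 0.0636 TPM (adjusted p = 0.0128; 0.102 without 2D replicate 1). LMX1A (Gene ID 4009) was too low to test, at 0 and 0.04 TPM in 2D and 0.92 and 0.97 TPM in 3D.

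In the GABAergic list 8 of 15 genes rose and none fell (adjusted p = 0.00151, and adjusted p = 0.604 with an estimated correlation), including the GABA-synthesizing enzymes GAD1 and GAD2. In the glutamatergic list 6 of 11 rose and none fell (adjusted p = 0.00769, and adjusted p = 0.604 with an estimated correlation). The members with the smallest adjusted p there were transcription factors of newly formed neurons, namely NEUROD1 (1.99 to 6.60 TPM, log2 fold change 1.35 ± 0.13), NHLH2 (3.75 to 8.17 TPM), NEUROD4 and NHLH1. In the serotonergic and noradrenergic list 4 of 7 rose (adjusted p = 0.0108, and adjusted p = 0.604 with an estimated correlation), among them FEV and TPH2. In the neural progenitor list 11 of 19 rose, led by VIM (1483 to 2021 TPM), and HMGA2 and PROM1 fell (adjusted p = 0.015, and adjusted p = 0.604 with an estimated correlation). In the hindbrain and HOX list 4 of 8 tested genes rose, HOXB9 from 0.555 to 2.92 TPM (adjusted p = 0.0216, and adjusted p = 0.614 with an estimated correlation). In the cholinergic list 3 of 6 rose (adjusted p = 0.0368, and adjusted p = 0.61 with an estimated correlation). Both of these last lists missed the threshold without 2D replicate 2 (adjusted p = 0.0596 for each) and without 3D replicate 1 (0.0742 for each).

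**Figure D2:**
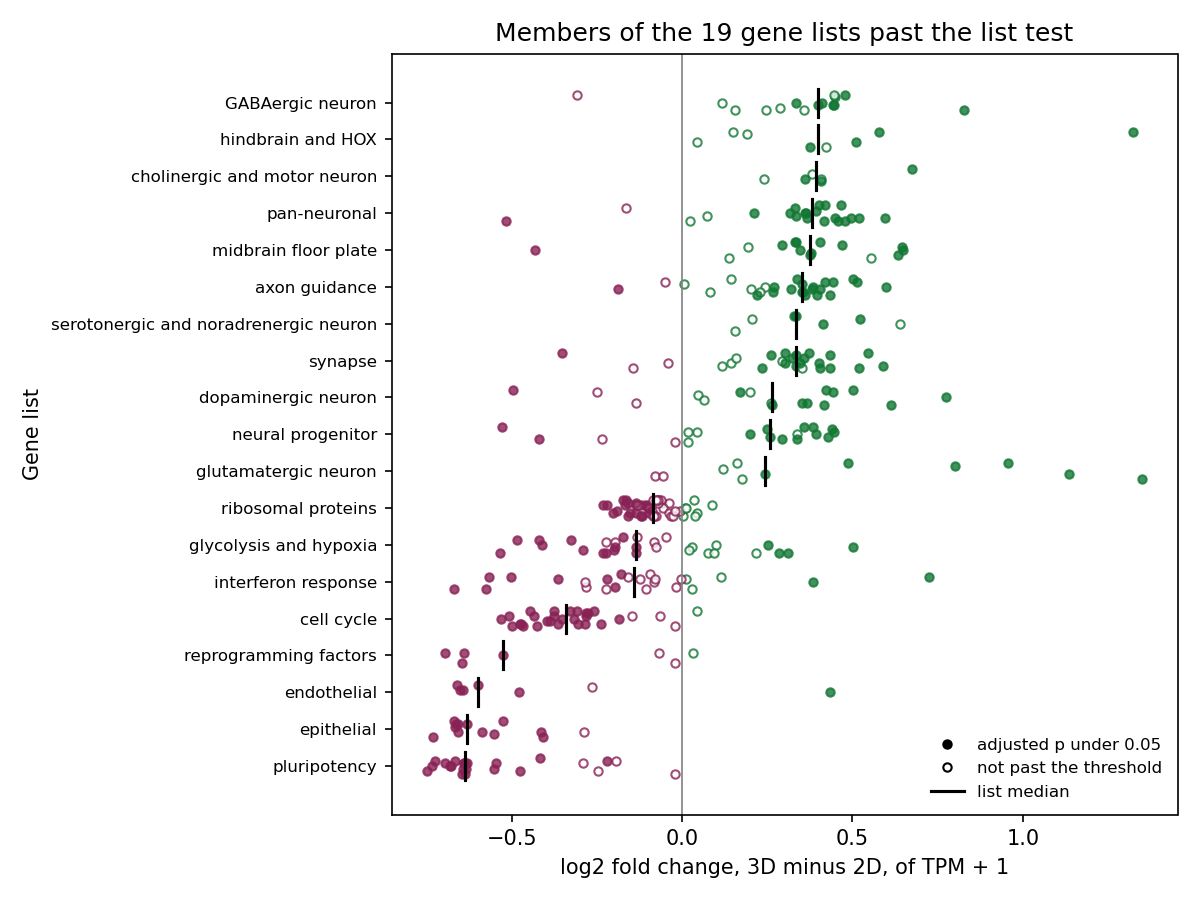
Log2 fold change (3D minus 2D, TPM + 1) of each tested member of the 19 gene lists past the list test, 1 point per gene, filled where its adjusted p was under 0.05, with the list median as a black bar. The vertical jitter carries no meaning. Pluripotency, epithelial and endothelial medians lie near -0.6, neuronal medians between 0.24 and 0.40, and the ribosomal protein median at -0.086.

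With LOC, LINC, antisense and clone names left out, the largest rises among genes of at least 5 TPM were those of TRH (Gene ID 7200, 2.25 ± 0.346 to 8.89 ± 0.700 TPM, log2 fold change 1.60 ± 0.12), TTR (Gene ID 7276, 55.6 ± 1.55 to 124.6 ± 3.75 TPM, log2 fold change 1.15 ± 0.050), PCDHGC4 (0.96), NHLH2 (0.96), PTGDS (0.94), HRC (0.90), NRN1 (0.89) and CFC1 (0.85). PCDHGC4 shares its last exons with other genes of its protocadherin cluster and CFC1 has a near-identical copy, so both are uncertain.

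Genes of other cell types and programs moved in both directions, and their lists did not pass. In the mesenchymal list 8 of 19 genes rose and 2 fell (adjusted p = 0.181), with the fibrillar collagens COL3A1, COL1A2 and COL1A1 (Gene ID 1277, 119.3 ± 0.891 to 142.9 ± 1.53 TPM) higher. In the matrix list 11 of 28 rose and 6 fell (adjusted p = 0.505). In the astrocyte list 5 of 15 rose and 4 fell (adjusted p = 0.625). GFAP (Gene ID 2670), the astrocyte filament protein, stood at 2.00 ± 0.0707 TPM in 2D and 2.12 ± 0.148 TPM in 3D (adjusted p = 0.794). In the integrin and focal adhesion list 5 of 24 fell, among them VCL and ACTN1, and 1 rose (adjusted p = 0.115; 0.0454 with a length and GC correction). YAP targets, which respond to mechanical tension, had 4 higher and 2 lower of 18 (adjusted p = 0.842). Among immediate early genes 8 of 16 rose, with FOS and JUN higher by 0.65 and 0.47 on the log2 scale, and FOSL1 fell (adjusted p = 0.124). The oxidative phosphorylation list had 4 higher and 4 lower of 35 (adjusted p = 0.339), and 3 higher and 3 lower adjusted over the list alone. In the lists tested other than this and the ion channels, the counts adjusted over the list alone were equal or larger.

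Of 43 lists tested, 19 passed with camera's preset correlation, 11 up and 8 down. None passed with an estimated correlation, where the smallest unadjusted p was 0.0769 and the smallest adjusted p 0.604. That form of camera has only the 2 residual degrees of freedom of the fit, and so low power. By limma's fry, which asks only whether a list's genes move on balance in 1 direction, 9 passed. Of these 9, 7 had passed camera and 2, forebrain and Notch (adjusted p = 0.0462 each), had not. Pluripotency (adjusted p = 0.0516) and cell cycle (adjusted p = 0.0507) missed the threshold by fry. Some lists share genes, so their results are not independent of each other.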

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

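The length and GC correction and the fit without robust moderation were chosen after seeing the data. No call among the 4979 changed genes took the opposite sign under median ratio scaling, or under the length and GC correction where its gene was tested. The other alternatives could not turn a sign, because in every changed gene both 3D libraries lay on the same side of both 2D libraries. Of 197 genes named or listed by the rule or after it, 28, 33, 20 and 2 lost their call without 2D replicate 1, 2D replicate 2, 3D replicate 1 and 3D replicate 2, and 0 to 21 under the other settings. The count of changed genes stayed within 1.5 times the 4979 under pseudocounts of 0.1 and 0.01 (4959 and 4943), no filter (4089), a stricter filter (4875), median ratio scaling (4725), limma without trend (3486), the length and GC correction (4919) and no robust moderation (4822). Median ratio scaling moved the share of changed genes that were higher from 57.5% to 47.5%, so neither direction can be called the more frequent. Leaving out 1 library gave 2769 to 5484 changed genes, 1689 to 3102 higher and 1080 to 2382 lower, where the group with a lone library is assumed to vary like the other. The low counts came without 2D replicate 1 (3198) and 2D replicate 2 (2769). An adjusted p under 0.01 left 2741 genes, 1559 higher and 1182 lower, and an absolute log2 fold change of at least 1 left 34, 26 higher and 8 lower, as stricter thresholds must. The replicate block gave 5165 genes, 2933 higher and 2232 lower. The differences between replicates 1 and 2 correlated at 0.0373 across genes between the 2D and 3D groups, over 2 pairs, so the numbers are not shown to pair the libraries. Of 19 gene lists, 0 passed with an estimated inter-gene correlation. The estimates were 0.68 for pluripotency and 0.464 for cell cycle, but below the preset 0.01 for 2 of the 19, which also lost their calls. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, so its power is low here. A call lost under it therefore does not by itself show that correlation between genes made the preset call false. With fry in place of camera 9 lists passed, 7 of the 19 and 2 others; the cause was not tested. The other alternatives gave 16 to 21 lists, the low end with fewer lists testable under the stricter filter. Limma without trend and limma without robust moderation leave the input of camera unchanged, so their 19 lists were fixed in advance. Tests and scalings that need counts were listed beforehand and not run because the files hold TPM. The unknown depth leaves the counting error of low genes unmeasured.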

Other observations

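The scan of symbol families and the tests of a smaller share of pluripotent-like cells were chosen after results had been seen, while the length and GC correction was added after seeing the data but before its outcome, and the gene lists were fixed beforehand.

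Genes that share a symbol stem, some of them members of the lists, also moved in groups. Of 175 such families with at least 10 tested genes, 13 passed camera at the preset correlation and none with an estimated correlation (adjusted p = 0.951 for each of the families named here). The replication helicase family MCM had 8 of 10 genes lower, nuclear pore genes (NUP) 12 of 22 lower and 1 higher, mitochondrial ribosomal genes (MRPL) 17 of 49 lower and 2 higher, and claudins (CLDN) 6 of 12 lower and 1 higher. Intraflagellar transport genes (IFT), which build cilia, had 8 of 18 higher and none lower (adjusted p = 0.0272), and CAMK kinases 5 of 10 higher and none lower (adjusted p = 0.0494). The MCM family shares members with the cell cycle list, and the claudins with the epithelial and endothelial lists, so these falls are not independent of them.

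Several genes at or near 0 TPM in 2D had higher values in both 3D libraries. PAX3, a factor of dorsal neural tube and neural crest, had 0.24 and 0.06 TPM in 2D and 1.92 and 2.22 TPM in 3D. HOXA9, which marks the posterior axis and was too low to test, had 0.06 and 0.17 TPM in 2D and 0.99 and 0.81 TPM in 3D. MYL1, a muscle myosin light chain, was listed at 0 in both 2D libraries and had 2.5 and 1.47 TPM in 3D. The opposite was seen in the histone gene H2AC14, at 2.38 and 1.13 TPM in 2D and listed at 0 in both 3D libraries. LOC128071544 was listed at 0 in both 2D libraries and had 32.0 and 17.1 TPM in 3D, and it was the only gene at 0 in both libraries of 1 group and at 2 TPM or more in both of the other. In the RefSeq table it lies within BCL9, which had 32.2 and 32.3 TPM in 2D and 31.8 and 31.0 TPM in 3D, so how reads were divided between the genes is unknown.

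The remaining lists did not pass at the preset correlation. Their rises and falls among tested genes were 5 and 0 of 11 for WNT targets, 6 and 2 of 18 for TGF-beta and BMP targets, 5 and 1 of 13 for hedgehog targets, 7 and 4 of 17 for the Notch pathway, and 6 and 2 of 22 for cholesterol synthesis. They were 2 and 4 of 14 for heat shock (adjusted p = 0.19; 0.0434 without 3D replicate 2), 3 and 5 of 20 for p53 and apoptosis, 6 and 5 of 25 for the unfolded protein response, and 0 and 1 of 10 for inflammatory genes. They were 3 and 1 of 11 for forebrain, 3 and 2 of 9 for choroid plexus, 4 and 3 of 15 for neural crest, 2 and 1 of 7 for muscle, and 2 and 1 of 11 for the oligodendrocyte lineage, where the test's direction was down while median and mean were above 0. Replication-dependent histones had 1 and 2 of 19 (adjusted p = 0.238; 0.0114 without 2D replicate 1) and mitochondrially encoded genes 1 and 3 of 13. Lists with too few tested genes were early endoderm and mesoderm (3 of 4 rose), microglia (1 of 2 fell) and blood (0 tested).

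Pluripotency genes were lower and neuronal genes higher in 3D. A bias of transcript length or GC content between libraries is argued against as the whole cause, since after a correction applied to 14008 genes 38 of the 39 changed members of the pluripotency and pan-neuronal lists stayed past the threshold in the same direction, with medians of -0.63 and 0.36. A smaller share of pluripotent-like cells in 3D is a candidate explanation, since 88.9% of pluripotency genes of at least 5 TPM (16 of 18) lay within 0.15 of a common log2 ratio of -0.65. For comparison, 70.3% of the 1824 other fallen genes lay as close to their own median of -0.32, with an SD of 0.156 against 0.19. Those genes were chosen for having fallen, which limits their spread, while the 0.19 includes SOX2 (-0.021) and CD24 (-0.22). The 2 spreads therefore cannot be compared. Of 11 epithelial genes of at least 5 TPM, 9 also lay within 0.15 of the pluripotency median. Pluripotent stem cells express some of the epithelial genes, such as CDH1 and KRT18, so these are not an independent comparison. Whether a common factor is particular to pluripotency genes is thus not shown either way. The exceptions, SOX2 and CD24, are also expressed by neural cells, but bulk TPM cannot separate fewer pluripotent cells from a lower level in each, nor from an effect of the scaffold on differentiation, which stays open.

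Genes that rose did so by different amounts, whereas a smaller share of pluripotent-like cells as the whole cause would raise the markers of all other cells by 1 common factor. There were 143 markers from the fixed lists of other cell types, each of at least 5 TPM on average. Of these, 3 (TTR, NHLH2 and DLK1) lay above the pan-neuronal median of 0.38. The test was one-sided and limma-based with Benjamini-Hochberg adjustment, and its result did not hold for all 3 without 2D replicate 2. A common factor equal to that median is argued against for these 3. The median would lie under the common factor if pluripotent-like cells also express pan-neuronal genes, which was not tested. Another 29 lay below the pan-neuronal median, which a common factor would also forbid unless pluripotent-like cells express them, and that was not tested. The 29 include SOX2, which is also a member of the pluripotency list. The added 1 TPM shrinks a fold but cannot turn a rise into a fall. It thus cannot account for those that were lower in 3D, such as GJA1 (-0.51) and FBLN1 (-0.27), while others, such as CALB1 (0.065), stayed above 0. The test was the last of 3 forms, each chosen after values had been seen. The first, on all 2634 genes of at least 5 TPM that rose (more than 0.3 and more than 3 standard errors above the median, unadjusted), counted 19 genes, past its limit of 10, and so argued against the explanation. The second, a one-sided limma-based test against 0.3 above the median with adjustment, counted 3, under its limit of 5. These were TTR, TRH (adjusted p = 0.00668) and LOC128071544, whose reads may be divided with BCL9. Markers under 5 TPM on average entered none of the 3 forms. With 3 markers also under the limit of 5 set for the last form, the outcome depends on the criterion. For risen genes of at least 5 TPM not named by the last 2 forms, share alone cannot be told apart from added changes. Risen genes under 5 TPM on average, NEUROD1 among them, were not tested, so no verdict is given for them.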
